A study of Mus musculus with 8 samples.

How the data were processed

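RNA of the microdissected CA1 subfield was measured on 8 one-colour (Cy3) Agilent arrays of 44397 spots, 4 arrays to a slide on 2 slides. RNA was extracted with TRIzol and labelled with Agilent's Low Input Quick Amp kit, per the labels' protocols. Scans were read with Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09), per the file headers. The deposited intensities used were each spot's processed signal, which the software had already corrected for background per the file headers, and the median spot and background intensities. A table of log2 values deposited with them was found, by setting each column against its array, to hold the log2 processed signals after quantile normalization over the 8 arrays: it differed from that by at most 0.00106, and each column had a median of 8.315. Its scale and centring follow from this, and the steps behind it are not given beyond limma 3.8.2, which the submitters' processing notes name. Array grids name the mouse assembly mm9, per the file headers, while the gene table used here follows GRCm38.p6, so it served for names, neighbours and gene lengths, and no coordinates are printed.

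Samples were grouped by the genotype and the number of pooled animals in the labels: 3 arrays of 3-animal pools per genotype, which were compared, and 1 array of a 9-animal pool per genotype, which was never tested. The labels describe the 3-animal pools of a genotype as different animals, so p-values measure the spread between pools. Slides were read from the array headers. Slide 1 held WT 1, WT 3, KO 1 and the KO pool, and slide 2 held WT 2, KO 2, KO 3 and the WT pool, each slide being 1 scan. The numbers after WT and KO were given here and only name arrays.

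The log2 processed signal was reduced by each array's 75th percentile over the 43020 spots that are not controls. Outlier-flagged spots were left out and spots of a probe averaged, which left 302 of 39429 probes without a value on some array. The files name probes by accession: 26055 probes matched the gene table by accession without version, giving 19751 genes, and other features keep their accession. Probes well above background on all 3 arrays of at least 1 genotype were kept (31194), and of several probes of a gene the one with the highest mean signal was tested. Of 151 named genes, 41 had other probes past the filter, and in 10 of these at least 1 probe had the opposite sign. Where a probe was not well above background on any array of a genotype, the fold is given as a bound: the mean of the bright genotype against the mean, over the arrays of the other, of the higher of the lowest signal well above background and the probe's own signal.

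Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate, 3.05 prior degrees of freedom) and Benjamini-Hochberg adjustment over 25443 features, and tables were handled with data.table version 1.17.8. Gene lists fixed before the data were examined, 1269 memberships of which 1155 were tested, were compared with camera at a preset correlation of 0.01 and adjusted over the 37 lists with at least 5 tested genes. They cover mitochondria and redox, synapse and channels, stress responses, hippocampal subfields, other cell types and genes linked to MeCP2. Camera with an estimated correlation and fry were run beside it. In 9 lists, none of them past the threshold, the median, the mean and the direction of the test differed in sign. The rule for named genes, also fixed beforehand, took Mecp2, the genes past the threshold whose arrays do not overlap, filled to 6 per direction with the smallest unadjusted p and then given as values, and up to 4 members of each list with the smallest p. Members of lists beyond these are named only where a count is spelled out.

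The fit was tested on simulated data, 10 sets of 25443 features in which 200 had a known difference. It recovered 37.8% of those of log2 size 1, 80.8% of size 2, 97% of size 4 and 99.2% of size 5. There were 5.5 false calls per 100 calls. With 200 changed features the adjusted threshold is easier to pass than with the 3 called in the real data. The recovered shares therefore do not give the power of the real comparison. In it, Etnppl (log2 difference 1.80, adjusted p = 0.0711) and Clcnka (1.80, 0.159) did not pass limma's test. The simulated genes varied independently of each other, and unshifted lists of them were called in 0 of 360 cases. This does not bear on lists of correlated genes, and other splits of the 6 real arrays gave up to 10 lists past the threshold. The precision is set by the 3 arrays per genotype. Alternatives were normexp with an offset of 50 and quantile normalization, on median spot intensities in place of the planned means, which the files lack, quantile and median scaling, the deposited log2 table, other filters and probe rules, trend and robust variance, array weights, and each array left out in turn. The slide as a block, each slide alone, the array position in the headers as a block and named probes alone were added after seeing the data. Figures were drawn with matplotlib 3.10.9.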

Results

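Gene expression was measured in the CA1 subfield of the hippocampus of male mice that lack MeCP2 (Mecp2-/y, the Bird knockout allele; KO) and of wild-type males (Mecp2+/y; WT), with oxidative burden and mitochondria named as the subject of the series. MeCP2 binds methylated DNA, and mutations of its X-linked gene cause Rett syndrome in people. CA1 was dissected from acute slices, and its RNA was hybridised to 1-colour Agilent arrays. Each of 3 WT and 3 KO arrays held the pooled RNA of 3 animals, so that 9 mice stood behind each genotype, and 1 further array per genotype held the pool of all 9. The average age behind an array was 46.0 to 46.7 days in WT and 47.0 to 47.7 days in KO, so that age differed slightly with genotype. The share of spots well above background lay between 79.4% and 86.9% over the 8 arrays, and no spot was saturated. The median processed signal lay between 217.2 and 538.3 in the WT arrays and between 293.2 and 357.5 in the KO arrays. Values are log2 signals relative to the 75th percentile of their array, and 25443 features were tested, 16634 of them with a gene symbol. With 3 arrays per genotype, the number of arrays limits the precision of every value.

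Mecp2 itself was 31.2-fold lower in KO. Its log2 signal was 2.08 ± 0.22 in WT and -2.88 ± 0.26 in KO (SD, n = 3 arrays each), and the probe stayed above background on all 3 KO arrays. The difference of -4.97 (SE 0.19) passed limma's moderated test with a Benjamini-Hochberg adjusted p of 0.000686, and every KO array lay below every WT array. Each array labelled KO was therefore low and each labelled WT was high. The array holds 1 probe for the gene (A_51_P424232), and whether it lies inside the deleted part is not given in the sources used here. With the slide as a block the difference was -4.93, and it was -4.87 within slide 1 and -4.99 within slide 2.

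Besides Mecp2, 2 features passed an adjusted p of 0.05 in limma's test. Irak1, a kinase of interleukin-1 receptor signalling whose gene is next to Mecp2 on the X chromosome, rose 2.96-fold in KO, from -0.25 ± 0.01 to 1.31 ± 0.04 (SD, n = 3 arrays each; log2 difference 1.56, SE 0.12, adjusted p = 0.0453). All 3 probes of Irak1 were higher, by 1.18, 1.49 and 1.56. An unnamed probe (A_55_P2112320), which lies outside the rule for named genes, fell at least 1.67-fold and was not well above background on any KO array (adjusted p = 0.0461). Its call was lost after normexp (0.338), where the log2 difference was -0.44 and so smaller than this bound, without the filter (0.194), with trend and robust variance (0.114), with the slide as a block (0.317) and with any array left out (0.0751 to 0.438). At an adjusted p under 0.10, 3 features were higher and 2 lower, the additions being Etnppl and a feature known only by its accession. Etnppl, an ethanolamine-phosphate lyase expressed in astrocytes, was 3.47-fold higher without passing 0.05 (log2 difference 1.80, SE 0.16, adjusted p = 0.0711). It passed after normexp (0.0290), with trend and robust variance (0.0351) and with array weights (0.00173), and not without the filter (0.269), with the slide (0.458) or the position (0.172) as a block, or with an array left out (0.0628 to 0.573). The Irak1 call was lost with any 1 of the 6 arrays left out (adjusted p 0.0707 to 0.455), without the filter (0.185), with all probes tested (0.0543), with the slide as a block (0.317) and with the array position as a block (0.146). Its difference kept its size, at 1.57 with the block, 1.58 within slide 1 and 1.56 within slide 2.

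The remaining genes with the smallest p in each direction did not pass the test, and their values are given as such. Higher in KO were Slc2a4, the insulin-responsive glucose transporter GLUT4 (log2 difference 1.38, SE 0.16), and Insm2, a zinc-finger factor (1.36, SE 0.16), whose other probe gave -0.06. Tshz2, a teashirt-family transcription factor, stood at 1.39 (SE 0.17), with 0.88 at its other probe. Clcnka, a kidney chloride channel, stood at 1.80 (SE 0.22). It was above background on 2 of the 3 WT arrays, its other probe gave 0.18, and its near-identical paralog Clcnkb makes its identity uncertain. Lower in KO were Oprk1, the kappa opioid receptor (-1.41, SE 0.18), and Catspere2, of a sperm calcium channel family with close paralogs (-1.48, SE 0.20), which was above background on 2 of the 3 KO arrays. Kera, Pnma5 and Tmem92 were not well above background on any KO array, and were at least 2.49-fold, 1.83-fold and 1.96-fold lower. These sizes depend on the processing. After normexp with an offset of 50 and quantile normalization, Oprk1 stood at -0.73, Catspere2 at -0.43, Insm2 at 0.66 and Clcnka at 0.64. Kera stood at -0.44, Pnma5 at -0.16 and Tmem92 at -0.29, all smaller than the bounds from the processed signal. Of the 151 named genes 15 were more than 1.5 times smaller in this setting, namely these 7, Ppbp, Lyz2 (-0.21), Kcnj2 (0.22), Zfp36 (0.34), Prss35 (-0.47), Grin2d (-0.19), Xdh (0.56) and Car9 (-0.47). For the 9 smallest-p genes that open this paragraph, from Slc2a4 to Tmem92, the adjusted p in limma's test lay at 0.159 or 0.178. Over all features, 1846 had an unadjusted p under 0.05, 753 of them higher and 1093 lower in KO, where 1272 were expected by chance. This count was not stable, at 1246 without WT 2, 1260 without KO 3, 4338 without WT 3 and 8654 with array weights. Splits that ignore genotype also gave more, at 1988 for WT 1, WT 2 and KO 1 against the rest. That split follows the first of the numbers that end the sample titles, whose meaning is not given. For WT 1, WT 2 and KO 2 against the rest the count was 3805, so the excess over 1272 cannot be credited to genotype. In 3427 features (13.5%) the 3 KO arrays all lay on one side of the 3 WT arrays, against a chance share of 10%.

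**Figure D1:**
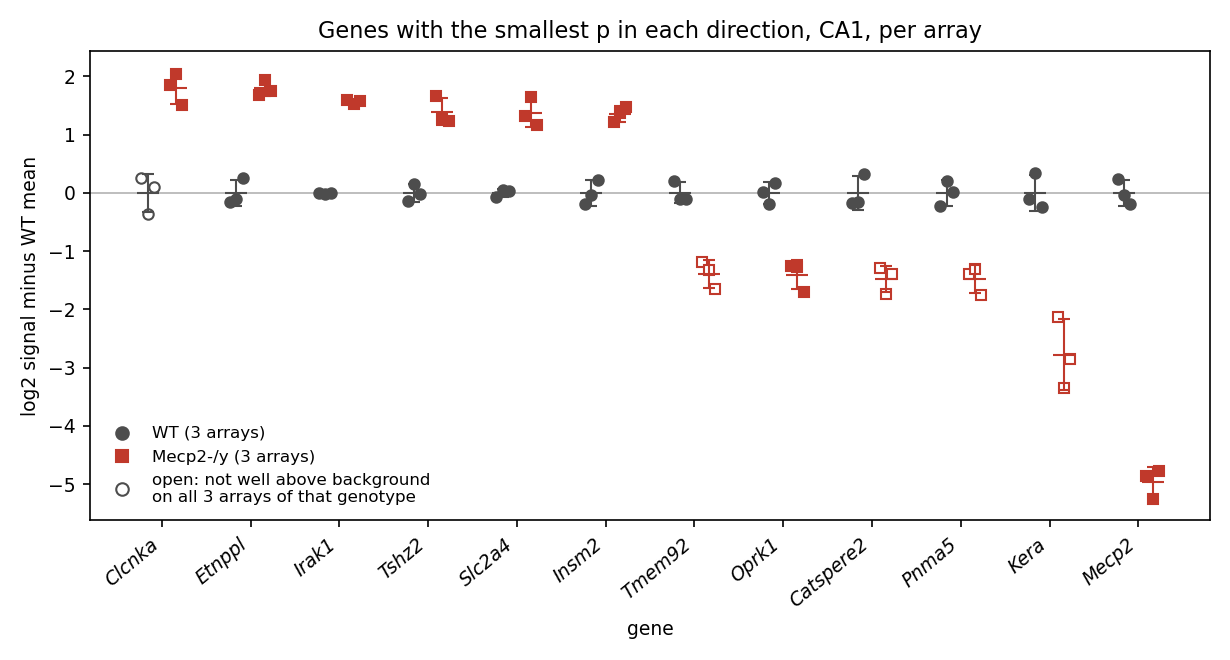
Log2 signal of each array minus the WT mean (vertical axis) for the 12 genes with the smallest p in each direction (horizontal axis), with WT arrays as circles, KO arrays as squares and bars for the mean ± SD of 3 arrays. Mecp2 lies at -4.97 and Irak1 at 1.56 from the WT mean, and open symbols mark a genotype in which the probe was not well above background on all 3 arrays.

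The subject of the series points to the genes of mitochondria and of oxidative stress, and no list of them passed camera's adjusted threshold. Of 87 nuclear genes of oxidative phosphorylation, 1 was higher and 0 were lower at an unadjusted p under 0.05, and none passed the adjusted threshold in limma's test. That gene was Cox15, which makes the heme of cytochrome c oxidase (log2 difference 0.49, SE 0.18). The median difference of the 87 was 0.02, with members from -0.29 (Ndufa10, of complex I) to 0.50 (Ndufa4, of cytochrome c oxidase, SE 0.40), and the median SE of a gene was 0.18. The median had no settled sign, since it was -0.01 after median scaling, -0.11 without WT 1 and 0.15 without WT 3. The count was 9 without WT 3 (6 higher, 3 lower), and 10 with array weights (7 higher, 3 lower), where 2 passed the adjusted threshold. The mean of the complex I genes was 3.78 ± 0.23 in WT and 3.76 ± 0.01 in KO (SD, n = 3 arrays each), so that the WT arrays differed from each other by more than the genotypes did. By list, complex I had a median of 0.00 over 36 genes (camera adjusted p = 0.960), complexes II and III 0.03 over 14 (0.823), complex IV 0.07 over 19 (0.334) and ATP synthase 0.01 over 18 (0.960). The 13 genes of the mitochondrial genome were not analysed here, as no probe was matched to them.

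Redox enzymes and other mitochondrial functions gave single genes at an unadjusted p under 0.05 and no list past the threshold. Among 53 antioxidant genes the 1 such gene was Hmox1, the inducible heme oxygenase (-0.46, SE 0.19), with -0.02 at its other probe and -2.47 between the 9-animal pools. Gpx1 stood at -0.34 (SE 0.15) and Nqo1 at 0.44 (SE 0.19), and the list had a camera adjusted p of 0.960. Of 22 genes whose enzymes produce reactive oxygen, Xdh, the xanthine oxidoreductase, was higher (0.89, SE 0.28) and Maob and Ptgs1 were lower (-0.48 and -0.34). This list reached an adjusted p of 0.970. Of 49 genes of mitochondrial dynamics and import, Prkn, the ubiquitin ligase parkin, was higher (0.41, with 0.09 at its other probe). The import factors Timm8a1 and Timm22 were lower (-0.39 and -0.36), and the list had a camera adjusted p of 0.960. Mrps25 (-0.49, with 0.32 at its other probe) and Mrpl43 (-0.33) were lower among 74 mitochondrial ribosomal proteins (list adjusted p = 0.823). The citric acid cycle with pyruvate dehydrogenase (30 genes, adjusted p = 0.960) and glycolysis (22 genes, adjusted p = 0.882) held 0 genes at an unadjusted p under 0.05. In the cytosol, the 78 ribosomal protein genes held none either (adjusted p = 0.370). The 43 proteasome genes held Psmd10 (-0.38, with -0.08 at its other probe), and the list had a camera adjusted p of 0.688. In simulated data of this design without correlation between genes, a list of 30 genes shifted by 0.3 was called in 10 of 10 simulations. The oxidative phosphorylation lists had estimated correlations between genes of 0.23 (complex IV) to 0.61 (ATP synthase). The simulation therefore does not show what shift would have been seen in them.

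Of the 37 gene lists tested with camera at a preset correlation of 0.01, 4 passed an adjusted p of 0.05, and all 4 were higher in KO. That number does not set the genotypes apart from other groupings. Of the 10 splits of the 6 arrays into 3 and 3, 7, the real one included, gave at least 4 lists, and the highest other gave 10. The immediate-early genes, which neurons switch on within minutes of activity, were the first of the 4 lists. Of 40 measured, 38 had a positive difference, with a median of 0.32 (1.25-fold; adjusted p = 9.73e-10, and adjusted p = 0.591 with an estimated correlation). The 6 at an unadjusted p under 0.05 included Ier2 (0.77, SE 0.20), Egr2 (0.74, SE 0.20), Zfp36 (0.75, SE 0.21) and Trib1 (0.55, SE 0.15), and none passed the adjusted threshold over the list alone. The mean of the list was -0.58 ± 0.15 in WT and -0.23 ± 0.09 in KO (SD, n = 3 arrays each). Its median was 0.27 with the slide as a block, 0.25 within slide 1 and 0.26 within slide 2.

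Genes induced by glucocorticoids were the next list. Of 24 measured, 22 had a positive difference, with a median of 0.27 (adjusted p = 2.86e-07, and adjusted p = 0.721 with an estimated correlation). Plin4, a lipid-droplet protein, stood at 1.71 (SE 0.48), Sgk1, a serum- and glucocorticoid-regulated kinase, at 0.68 (SE 0.20), and Fkbp5, a co-chaperone of the glucocorticoid receptor, at 0.57 (SE 0.16). No member passed over the list alone. The list's median was 0.22 with the slide as a block, and its call was lost within slide 1 (0.14, adjusted p = 0.151) and not within slide 2 (0.36). With an array left out the median lay between 0.16 (without WT 1) and 0.47. It shares 1 gene with the immediate-early list.

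The other lists past the threshold hold markers of tissue that borders on CA1. Of 24 markers of meninges and fibroblasts, 20 had a positive difference, with a median of 0.40 (adjusted p = 6.31e-06, and adjusted p = 0.721 with an estimated correlation). Col6a2 (1.17, SE 0.16) and Islr (1.00, SE 0.18) passed when adjusted over the list alone, and Ogn stood at 1.29 (SE 0.35) and Col6a1 at 0.88 (SE 0.27). The median was 0.60 within slide 2 and 0.09 within slide 1, where the call was lost (adjusted p = 0.149), and it was 0.32 with the slide as a block and 0.13 without KO 3. Of 21 markers of thalamus and neocortex, 16 had a positive difference, with a median of 0.27 (adjusted p = 0.00106, and adjusted p = 0.591 with an estimated correlation). Over the list alone Tshz2 was higher and Rspo1, a secreted Wnt agonist, was lower (-0.73, SE 0.17). Slc17a6, the vesicular glutamate transporter of thalamic neurons, stood at 0.66 (SE 0.19) and Tbr1, a factor of deep-layer cortical neurons, at 0.66 (SE 0.21). The call was lost without WT 3 (adjusted p = 0.0567) and within slide 2 (0.11, adjusted p = 0.164), while the median was 0.29 within slide 1, 0.22 with the block and 0.15 without KO 1. Ttr, an abundant transcript of choroid plexus, stood at 2.53 (SE 0.81) on the same arrays. None of the 37 lists passed with an estimated correlation or with fry's directional test, which asks whether the genes of a list shift together without comparing them with other genes.

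**Figure D2:**
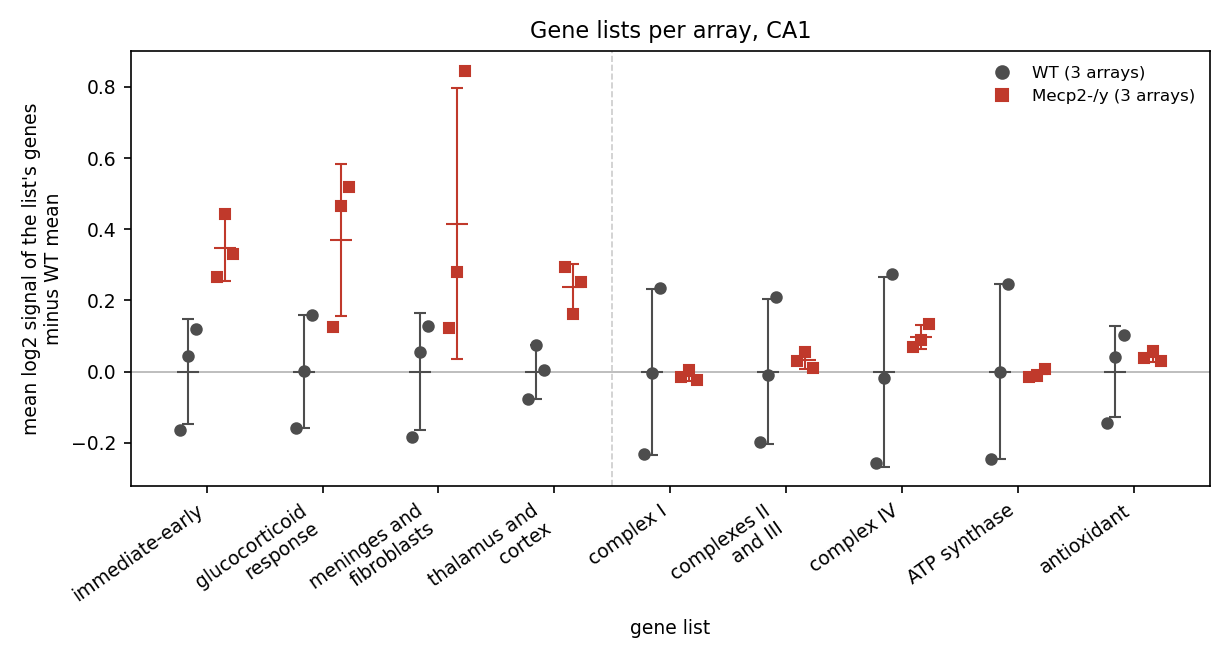
Mean log2 signal of the genes of a list on each array minus the WT mean (vertical axis) for the 4 lists past the preset camera threshold and for 5 lists of oxidative phosphorylation and antioxidant genes (horizontal axis), with WT arrays as circles, KO arrays as squares and bars for the mean ± SD of 3 arrays. The immediate-early list lies 0.35 above the WT mean in KO, and in the oxidative phosphorylation lists the 3 KO arrays lie inside the range of the WT arrays.

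Neuronal lists did not pass as lists, and their genes with the smallest p are given as values. Over all 25443 features 1846 had an unadjusted p under 0.05, an excess that cannot be credited to genotype. A few such genes would thus be found in most lists of this size. Cacna1g, the T-type calcium channel Cav3.1, was lower by a log2 difference of -1.02 (SE 0.14) and passed when adjusted over its list of 42 calcium-handling genes alone, not over all genes (adjusted p = 0.178). Its other probe gave -0.54, and Calb1, the calcium buffer calbindin, stood at -0.54 (SE 0.14; list adjusted p = 0.960). Of 21 genes of GABA signalling, 15 had a negative difference. Gabra2 (-0.59, SE 0.18) and Gabra3 (-0.39, SE 0.15), subunits of the GABA-A receptor, had an unadjusted p under 0.05 (list adjusted p = 0.207). Of 39 glutamate receptor genes, 4 were lower and 0 higher at that level, namely Gria4 (-0.52), Grm3 (-0.59), Cacng2 (-0.48) and Grin2d (-0.37; list adjusted p = 0.823). Of 52 potassium channel genes, 5 were higher, among them Kcnj2 (0.74) and Kcns1 (0.64), and 2 were lower, among them Kcnj16 (-0.48; list adjusted p = 0.334). Of 38 synaptic vesicle genes, Doc2a (-0.74) and Unc13b (-0.46) were lower and Slc17a6 was higher (list adjusted p = 0.364). Of 30 interneuron markers, Npy2r (-0.58) and Tac1 (-0.67) were lower and Dlx5 (0.71) was higher (list adjusted p = 0.960).

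Markers of the subfields and of other cells gave the following values. Of 16 markers of CA1 pyramidal cells, 1 was at an unadjusted p under 0.05, Satb2 (0.75, SE 0.25; -0.23 in the 9-animal pools), and the mean of the list was 0.73 ± 0.11 in WT and 0.74 ± 0.00 in KO (SD, n = 3 arrays each; list adjusted p = 0.960). Of 17 markers of CA3 and CA2, 2 were higher and 3 lower, and Prss35 (-0.97, SE 0.18) passed over the list alone (list adjusted p = 0.207). Of 21 dentate gyrus markers, C1ql3 (0.75) and Stxbp6 (0.57) were higher and Calb1 was lower (list adjusted p = 0.207). The mean of this list was -0.49 on KO 3, against -1.08 on KO 1, -1.14 on KO 2 and -1.28 to -1.11 on the WT arrays. Astrocyte markers (30 genes, 1 higher and 2 lower), oligodendrocyte markers (35 genes, 0 and 2) and microglia and macrophage markers (30 genes, 0 and 2) had adjusted p of 0.882, 0.882 and 0.207. Fcrls (-0.78) and Lyz2 (-0.71) were the microglial and macrophage genes. Of 31 endothelial and pericyte markers, Vwf, the von Willebrand factor of endothelium, was higher by 0.84 (SE 0.14) and passed over the list alone (list adjusted p = 0.0525). Of 17 blood cell markers, Ppbp of platelets was at least 2.28-fold lower and passed over the list alone, with a log2 difference of -0.30 after normexp that is smaller than this bound, and Hbb-b2 stood at 0.33 (list adjusted p = 0.747).

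Genes reported in earlier work to respond to MeCP2 were a list fixed before the data were examined, and 31 were measured. Of these, 14 had an unadjusted p under 0.05, 8 higher and 6 lower in KO, and 8 passed when adjusted over the list alone, against 1 (Irak1) over all genes. The 8 were Irak1, Oprk1 (-1.41, SE 0.18), the differentiation inhibitors Id3 (0.85, SE 0.14) and Id1 (0.85, SE 0.19), corticotropin-releasing hormone Crh (-0.60, SE 0.15), the creatine-synthesis enzyme Gamt (-0.56, SE 0.16), and Fkbp5 and Sgk1, which are also among the glucocorticoid-induced genes. Bdnf, the neurotrophin most often studied as a target, stood at -0.22 (SE 0.17). Since members went both ways, camera gave no call (adjusted p = 0.152), whereas fry's test for change in either direction gave an adjusted p of 7.56e-06 without comparing the list with other genes. With the slide as a block 10 were at an unadjusted p under 0.05 and 3 passed over the list alone. Within slide 1, with 3 arrays, the counts were 3 and 0, and within slide 2 they were 10 and 1. Without KO 3 the counts were 9 and 4, without KO 2 they were 12 and 3, and without WT 2 they were 10 and 4. Other settings gave more, with counts of 16 and 6 without WT 3, 14 and 11 after normexp, and 22 and 22 with array weights. The neighbours of Mecp2 on the X chromosome (52 genes), markers of CA3 and CA2, markers of thalamus and neocortex, and interferon-response genes also passed fry's test for either direction (adjusted p 6.84e-05, 0.00229, 0.00272 and 0.01). Among the neighbours 5 genes were higher and 3 lower at an unadjusted p under 0.05, and camera gave an adjusted p of 0.970. Irak1 is among the 5 and was the 1 neighbour that passed when adjusted over the list alone. Of all 52, 22 had a positive and 30 a negative difference.

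**Figure D3:**
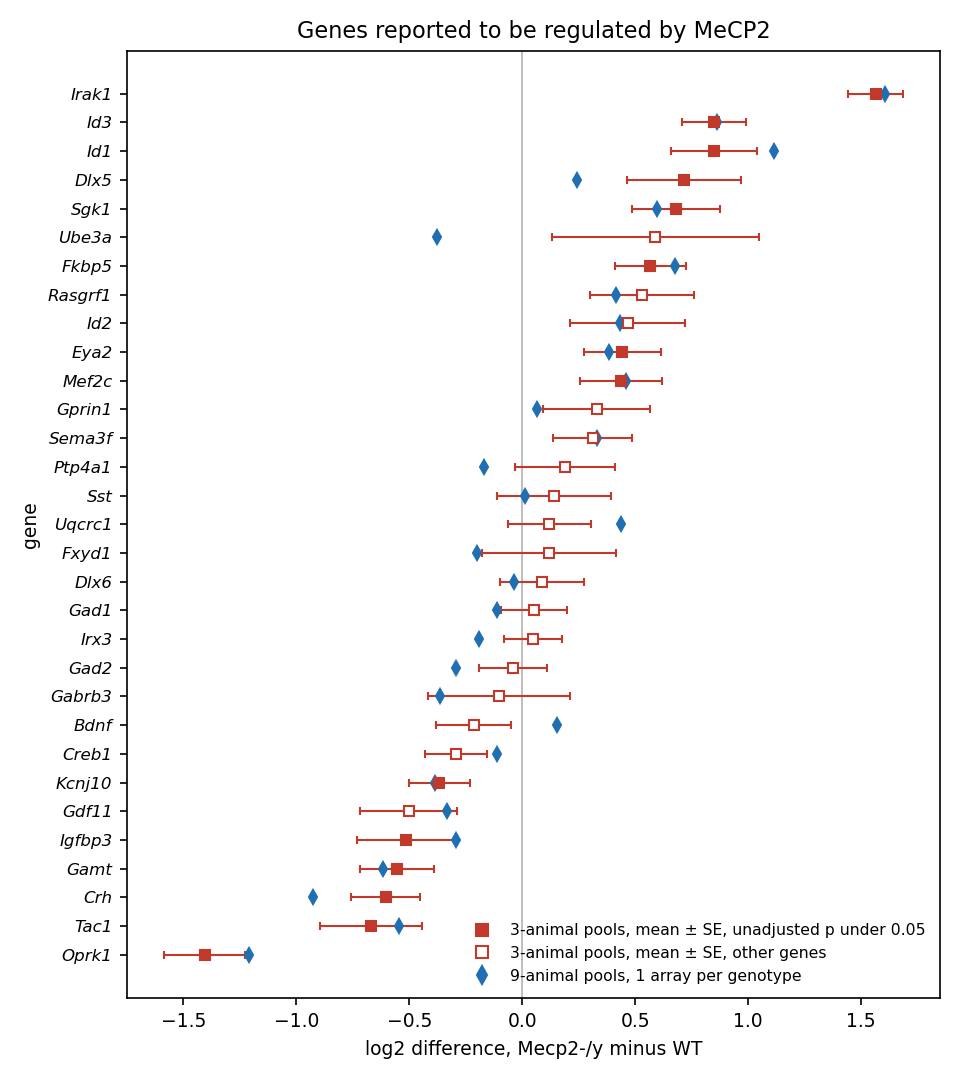
Log2 difference of KO minus WT (horizontal axis) for the 31 measured genes reported to respond to MeCP2 (vertical axis), as the mean ± SE over 3 arrays per genotype (squares, filled at an unadjusted p under 0.05) and for the single pair of 9-animal arrays (diamonds). The 14 filled genes run from Oprk1 at -1.41 to Irak1 at 1.56, and the 9-animal pools gave -1.21 and 1.61 for these.

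The arrays of the 9-animal pools hold RNA of the same animals and so repeat the labelling and hybridisation, not the animals. Mecp2 was lower by -4.23 and Irak1 higher by 1.61 between them, and Etnppl stood at 1.83, Plin4 at 2.01 and Ttr at 2.57. Of the 552 features at an unadjusted p under 0.01 on the 6 arrays, 540 (97.8%, exact 95% interval 96.2% to 98.9%) had the same sign in the pools, against 65.6% of the other features. Across those features, which are not independent replicates, the differences correlated with r = 0.907, and over all 25431 compared with r = 0.400. There is 1 array per genotype here and no test, and the KO pool lay on slide 1 and the WT pool on slide 2.

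Long genes have been reported to be higher without MeCP2, and the difference seen here was small. The mean log2 signal of 2174 genes longer than 100 kb (gene models of GRCm38.p6, a later assembly than that of the array) exceeded that of the 14460 others by 0.36 ± 0.01 in WT and 0.42 ± 0.03 in KO (SD, n = 3 arrays each). This gap was 0.06 larger in KO, and all 3 KO arrays lay above all 3 WT arrays. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The median log2 difference was 0.02 for the long genes and -0.02 for the others. From the lowest to the highest of 4 classes of signal these medians were 0.07 and -0.05, 0.04 and -0.01, 0.03 and -0.02, and 0.00 and -0.01. With a limit of 50 kb the gap was 0.04 larger in KO than in WT, and with 200 kb 0.09 larger.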

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

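The slide as a block, each slide alone, the array position as a block and probes with a gene symbol alone were chosen after seeing the data; the other settings were fixed before. The lower Mecp2 signal kept its side of the threshold in 17 of 19 settings, with -5.06 to -4.82 when 1 array was left out. It missed it within slide 1 (-4.87, adjusted p = 1.00) and within slide 2 (-4.99, adjusted p = 0.449), where 3 arrays remain and the lone array is assumed to vary like the others. Its adjusted p lay between 1.56e-05 and 1.00. The 3 features past the threshold became 1 without the background filter, 1 with all probes tested 1 with the slide as a block and 1 with the array position as a block, 0 within slide 1 and 0 within slide 2, 1 to 2 with an array left out (1 without WT 1, WT 2, KO 1, KO 2 or KO 3), and 3108 with array weights, of which 1267 were higher. Array weights gave WT 2 a weight of 6.73 against 0.299 for WT 1 and 0.298 for WT 3, and the cause of these changes was not tested. The adjusted p of Irak1 lay between 0.00153 and 1.00 over all settings. The 4 gene lists past the threshold became 8 without WT 1 (4 to 8 with an array left out), 0 for camera with an estimated correlation and 0 for fry, and none reversed. Lists that gained the threshold include the heat-shock list without the filter (adjusted p = 0.0410, between 0.00782 and 0.679 over the settings) and the endothelial list after median scaling (0.0302, between 0.00635 and 0.637). The share of the same sign in the 9-animal pools was 94.2% after quantile normalization, 91.9% after normexp and 94.2% in the deposited log2 table. The gap of long genes was larger in KO than in WT by 0.0948 for genes over 200 kb, 0.0374 for genes over 50 kb and 0.04 to 0.07 with an array left out. Of the named genes over all settings, 14 values lost and 95 gained the threshold, and none reversed; most of the gains came with array weights. For the animals, no paired analysis was possible because the labels give no number known to pair a WT with a KO pool, and accession order does not pair arrays. The block on the numbers that end the titles was not run, since these do not match the positions in the headers. The first of these numbers is spread unevenly over the genotypes, so an effect tied to it was not separated from genotype. The header positions, which place 1 WT and 1 KO array at each of 3 positions, were used as a block in its place. This position block pairs arrays by their place on the slide, not animals. With it, Mecp2 stayed past the threshold (adjusted p = 0.0158), as did the 4 lists. Probes near background limit Kera, Pnma5, Tmem92, Ppbp, Clcnka and Catspere2 to bounds or partial measurement.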

Other observations

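Of the tests here, the random lists for the genes reported to respond to MeCP2, the neighbours on the X chromosome and the array-by-array comparison of choroid plexus genes were chosen after the result was seen. Among 27 markers of choroid plexus and ependyma, which line the ventricle, 3 were higher and 5 lower at an unadjusted p under 0.05 (camera adjusted p = 0.960). The higher ones were the choroid plexus genes Ttr (log2 difference 2.53, SE 0.81), Kcne2 (1.34, SE 0.50) and Aqp1 (0.95, SE 0.40). The lower ones were mostly genes of ciliated ependymal cells, Ccdc153 (-0.84, SE 0.25), Dynlrb2 (-0.72, SE 0.20), Tmem212 (-0.65, SE 0.22), Rarres2 (-0.40, SE 0.13) and Igfbp2 (-0.76, SE 0.22). All 8 had the same sign in the 9-animal pools. Array by array, Ttr followed the mean of 10 other choroid plexus genes, in 1 relation computed over 6 arrays (Pearson r 0.935, exact permutation p = 0.00972; r 0.757 without the 2 farthest arrays and 0.869 within genotypes), and KO 1 (1.54) lay below WT 2 (1.64).

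Lists of other responses did not pass as lists with the processing of the report. Of 27 cholesterol synthesis genes, 5 were lower and 0 higher at an unadjusted p under 0.05, namely Ebp (-0.49, SE 0.13), Idi1 (-0.54, SE 0.16), Tm7sf2 (-0.43), Sqle (-0.36) and Msmo1 (-0.40; list adjusted p = 0.207). Of 24 hypoxia-inducible genes, P4ha1, a collagen prolyl hydroxylase (-0.85, SE 0.19), and Car9, a carbonic anhydrase (-0.76, SE 0.18), were lower and passed over the list alone (list adjusted p = 0.823). Of 35 interferon-response genes, Ifitm2 (1.05, SE 0.16) passed over the list alone and Xaf1 stood at 0.44 (list adjusted p = 0.207). Of 30 heat-shock and chaperone genes, Hsph1 (-0.40), Ahsa1 (-0.32) and Hsp90aa1 (-0.37) were lower and Bag3 (0.45) was higher (list adjusted p = 0.0972).

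Of the 10 splits of the 6 arrays into 3 and 3, 1 (the real one) gave 3 features past the threshold and the highest other gave 1. For gene lists, 7 of the 10 splits gave at least the real 4, and the highest other gave 10. The split with 10 lists set WT 1, WT 2 and KO 1 against the rest. It follows the first of the numbers that end the sample titles, and a batch behind that number was not tested. The split by slide gave 1 feature and 7 lists, and with the slide as a block the real split gave the same 4 lists as without it. Within slide 1 the lists past the threshold were the immediate-early, thalamus and neocortex, interferon, and CA3 and CA2 lists, and within slide 2 the immediate-early, glucocorticoid, meninges and synaptic vesicle lists. These calls within a slide rest on 1 array of KO (slide 1) or of WT (slide 2) at the preset correlation and carry little weight. With 10 splits no share under 0.05 is possible. The split of WT 1, WT 2 and KO 2 from the rest gave 3805 features at an unadjusted p under 0.05 against the real 1846. This points to a structure of the arrays other than genotype. By root-mean-square log2 difference, WT 3 was nearer to KO 3 (0.406), KO 1 (0.458) and KO 2 (0.514) than to WT 2 (0.526) or WT 1 (0.740).

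The immediate-early genes were higher in KO (adjusted p = 9.73e-10, and adjusted p = 0.591 with an estimated correlation), with 6 of 40 members at an unadjusted p under 0.05 and none past the adjusted threshold over the list alone. A slide effect is argued against by a median of 0.274 with the slide as a block over the 6 arrays. The lowest median over the block and both slides was 0.245, within slide 1, which holds 1 KO array. The list means of its WT arrays were -0.746 and -0.461, so the value within that slide carries little weight by itself. A single array standing apart is argued against by a lowest median of 0.265 with any array left out. Meningeal or vascular cells cannot be told apart from a change in neurons, since the 6 neuron-restricted members had a median of 0.383 but their array means overlapped between genotypes. These 6 ran from -0.06 (Homer1) to 0.47 (Egr4), each at an unadjusted p above 0.05 in limma's test. Neuronal activity of the genotypes and handling during dissection were not tested, and stay open.

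Markers of meninges were higher in KO (adjusted p = 0.721 with an estimated correlation), Ttr stood at 2.53 without passing, and dissection may have carried different amounts of meninges or choroid plexus. For meninges, the 5 abundant transcripts Dcn, Ptgds, Igf2, Col1a2 and Col3a1 had a median of 0.429, above the bound set beforehand, but Dcn stood at -0.33 and, by a requirement added later, their means should not have overlapped between genotypes, which they did, so this stays open. KO 3 alone carried much of it, since the median was 0.40 with it and 0.126 without it. In the mean of the list KO 1 (-2.26) lay below WT 3 (-2.25). The median of 0.126 lies above the bound set beforehand, but by less than its spread over the members (0.0392 to 0.213). That spread was not part of the bound set beforehand, and with it an array standing apart stays open too. The mean of the dentate gyrus list was also highest on KO 3 (-0.49). For Ttr, 10 other choroid plexus genes had a median of 0.563, between the bounds set beforehand, which leaves choroid plexus in KO as a group undecided. The ranks of the 6 arrays by Ttr and by these genes were close (Spearman rho 0.943, exact permutation p = 0.0167), which is consistent with a content of choroid plexus that varies from array to array.

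The genes reported to respond to MeCP2 held 14 at an unadjusted p under 0.05, where 10000 random lists of like signal held 2 in the median and 8 at most (share 1e-04, the smallest they can give), and the other splits of the arrays gave at most 3. Chance draw of genes is thus argued against, and that loss of MeCP2 lies behind these differences was not tested. The count of 14 ignores sign, and whether each gene moved in the direction reported earlier was not examined. For Irak1, next to Mecp2, a segment of the other strain's DNA kept around the targeted gene is a candidate explanation. Of the 50 nearest tested genes 7 (14%) had an unadjusted p under 0.05, and Irak1 itself was 1 of these 7. Among 548 other X-linked genes the share was 8.94% (Fisher's exact test, p = 0.305), so the segment and an effect of MeCP2 cannot be told apart. An effect of the deletion itself on the adjacent gene also stays open and was not tested.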
